A study of Oryza sativa with 6 samples.

How the data were processed

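RNA from rice root tips was measured on 6 Affymetrix Rice Genome arrays, 3 from seedlings before aluminium (Al) was given and 3 from seedlings after Al. Per the labels' protocols, seeds of a Japonica rice were germinated in water and the seedlings floated on 0.5 mM CaCl2. At 5 d of age they were moved to 0.5 mM CaCl2 with 50 µM Al at pH 4.5 for 6 h, and tips of 0 to 1 cm were taken. Total RNA was isolated with TRIZOL and a column kit with DNase, and 6 µg was used for biotin-labelled cRNA. The labels call the 3 samples of each group biological repeats. Whether each repeat was a separate culture is not given in the sources used here, so p-values measure the spread between these samples.

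2 deposited tables were read. The deposited value table holds log2 signals for 57258 probe sets, and the second table repeats the same log2 signals (largest difference 0.0). The submitters' processing notes name MAS5 for the signals, and its version and scaling target are not given in the sources used here. The linear values of the 6 arrays had nearly equal trimmed means, from 497.0 to 497.2, so each array had been scaled to a common level before deposit. Probe sets at the lowest value, 0, numbered 1363 to 2184 per array. Per the file headers, the second table also gives a detection call (present, marginal or absent) for each array, a p-value and a fold change. The deposited p-value equalled a test with unequal variances on the log2 values to within 1.5e-13 and was not adjusted. The deposited fold change was the ratio of mean linear signals, to within 7.7e-15 on the log2 scale. These columns of the authors' deposited table were used only for the counts credited to it in the report.

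Genes were named through the annotation column of the deposited table, which assigned 45882 probe sets to 1 gene, 1416 to several and 9960 to none, and named 37390 genes. No gene was named from a probe set assigned to several. Locus identifiers and product descriptions are those of that annotation and can be old. Gene symbols such as STAR1 were written beside the locus identifiers from prior knowledge. Of 23481 RefSeq accessions in the annotation, 0 matched the reference gene table of assembly GCF_034140825.1, so that table was not used. Coordinates are the probe set alignments of the deposited table, and their genome build is not given in the sources used here.

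Log2 signals were used as deposited. Probe sets called present on at least 3 of the 6 arrays, whatever their group, were tested, and no Affymetrix control probe set was in the tables. The test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, on the 2 groups without a covariate, with Benjamini-Hochberg adjustment over all probe sets tested and an adjusted p threshold of 0.05. Each probe set had 4 residual degrees of freedom, and 9.47 after the spread was shared across probe sets. Positive log2 changes are higher after Al. Standard errors are those of the limma fit. For a gene with several probe sets, the one with the highest mean signal stood for it. Probe sets with names ending in _s_at, _x_at or _a_at are marked as shared and may also measure similar transcripts. They were tested like the others. A probe set called absent or marginal on every array of a group has only a bound on its fold change. The bound sets the mean of the group where it was present against, per array, the higher of its own signal and the lowest signal called present. It is printed as "at least N-fold" and is not a lower confidence limit. Where a gene's own signals lay above the lowest signal called present, the bound is the fold between the group means and leaves out their spread. The lowest signals called present were 2.07 to 2.98 on the log2 scale. Probe sets present on no array had medians of 2.73 to 3.10, so those lowest signals are not a detection limit.

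Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 39 lists of at least 5 measured genes. The test was repeated with a correlation estimated for each list, and only the core Al tolerance and ART1-dependent lists passed at that setting. Camera then also tests on the 4 residual degrees of freedom of the arrays, which raises p-values by itself. The ABC transporter list went from adjusted p = 0.00345 to 0.153 at an estimated correlation of -0.0249, below the preset 0.01. A pass lost at that setting thus does not measure correlation between genes alone. Lists came from prior knowledge of rice genes (locus lists) or from words in the product descriptions (families), and were written before the data were examined, as were the test, the filter and the rule for named genes. That rule took the 12 largest rises and 12 largest falls among genes that passed the test, whose groups did not overlap and whose product was informative. It also took every measured core Al tolerance and clock gene, the markers of root tissues, and up to 4 passing members, by adjusted p, of each list that passed or had at least 5 calls. It named 174 genes.

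The fit was tested on simulated data with the arrays' own means, in which 200 of 25283 probe sets were changed. Noise was normal and independent, with spreads averaged over probe sets of like brightness. The fit recovered 50% of changes of 0.5 on the log2 scale, 82% of changes of 1, 96% of changes of 2 and 94% of changes of 3. It called 9 of 25083 unchanged probe sets. In the real data spreads were not averaged and 30.2% of probe sets were called, so these shares describe a simpler case. Signals of single probe sets carry no count, so the number of arrays limits the precision. Alternatives were quantile normalization, centring on the array median, no filter on dim probe sets, presence on all 6 arrays, an offset of 16 before log2, eBayes without the trend, the repeat number as a block, each array left out in turn, an estimated correlation in camera, and another rule for the probe set of a gene. Fits without 1 array kept the filter set on all 6 arrays. The planned use of the second table's values in place of the first was void, because the values are the same. Random lists, shuffled gene orders and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.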

Results

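Transcript levels in root tips of Japonica rice seedlings were compared before and after 6 h in 50 µM Al at pH 4.5. Al is a rhizotoxic metal ion in acid soils, and rice is among the most Al-tolerant cereals. The comparison asked which genes of the root tip (0 to 1 cm) differ in level after Al. Each group held 3 arrays. Between 24836 and 25492 of 57258 probe sets were called present per array, with 24877 ± 46.3 (SD, n = 3) before Al and 25274 ± 248 (SD, n = 3) after it. Across the tested probe sets, arrays of one group correlated at 0.987 and arrays of different groups at 0.951 to 0.956, and probe sets are not independent replicates. No array of tips kept for 6 h without Al was used here, so Al and the time in solution differ together between the groups. The pH of the solution before Al is not given in the labels, so pH may differ with them.

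All 12 measured genes of the core Al tolerance list were higher after Al. OsFRDL4, a citrate transporter that releases citrate from the root, was not called present on any array before Al. It was present on all 3 arrays after Al, at 10.35 ± 0.24 (log2 signal, SD, n = 3). That was at least 54.8-fold higher (33.0-fold without the second array before Al), and the 95% interval of its log2 change ran from 4.64 to 6.91. STAR1, the ATP-binding subunit of a transporter needed for Al tolerance, rose by 1.86 ± 0.06 (log2 change, SE), and its membrane partner STAR2 rose by 0.90 ± 0.06. Nrat1, the plasma membrane Al transporter, rose by 0.97 ± 0.05, and OsALS1, the tonoplast transporter that moves Al into the vacuole, by 1.00 ± 0.05.

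OsCDT3, a small cysteine-rich peptide called present on 2 of the 3 arrays before Al, rose by 1.43 ± 0.18, and OsFRDL2, a relative of OsFRDL4, by 1.04 ± 0.07. The transcription factors ASR1 and ASR5 rose by 0.94 ± 0.11 and 0.49 ± 0.08, and the expansin OsEXPA10 by 0.52 ± 0.09. All 12 passed when adjusted over the list alone, and the list passed camera (adjusted p = 2.16e-09, and adjusted p = 0.0476 with an estimated correlation). ART1 itself, the zinc finger factor that controls many of these genes, rose by 0.35 ± 0.10 (limma, adjusted p = 0.0210). The ART1 call was lost without the third array after Al (limma, adjusted p = 0.0639), without the first or the second array before Al (0.0560 and 0.0802), and without the intensity trend (0.0570). The magnesium transporter OsMGT1 rose by 0.76 ± 0.20 (limma, adjusted p = 0.0159), a call lost without the second array after Al (0.0592) or the second before it (0.0543).

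**Figure D1:**
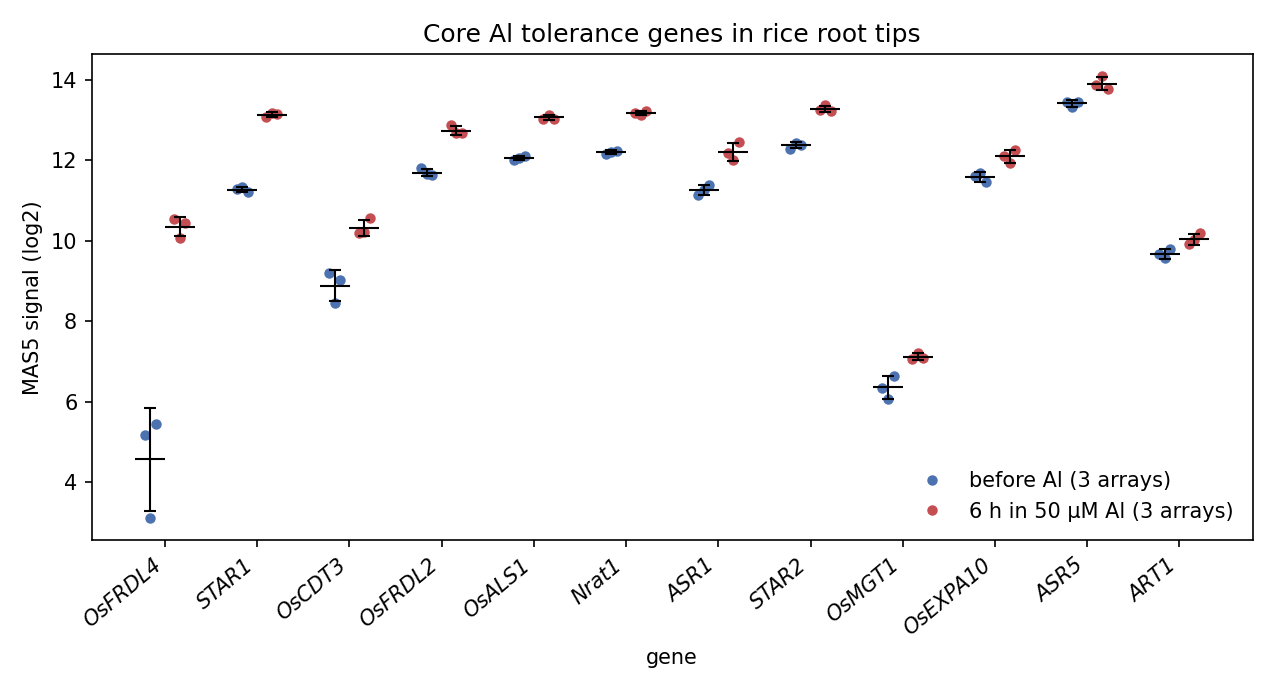
MAS5 log2 signal (vertical axis) of the 12 measured core Al tolerance genes (horizontal axis) on each array. Blue points are the 3 arrays before Al and red points the 3 arrays after 6 h in Al, with horizontal bars at the means and vertical bars for ± 1 SD, and the arrays after Al lie above those before Al in each of the 12 genes.

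Genes known from earlier work to depend on ART1 rose as a group. Of 21 measured, 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 change of 1.16 and 13 genes at least 2-fold higher. The list passed camera (adjusted p = 4.4e-14, and adjusted p = 0.0361 with an estimated correlation). It shares 8 genes with the core list, and of its 13 other genes 10 rose. Among these, LOC_Os02g53130, described as a nitrate reductase, rose by 3.21 ± 0.14, and Os04g0419100, without a product description and called present on 2 of the 3 arrays before Al, by 2.97 ± 0.13. The list of metal ion transporters, which includes Nrat1, had 11 higher and 0 lower of 25 (11 and 0 adjusted over the list alone). It passed camera (adjusted p = 0.00110, but adjusted p = 0.181 with an estimated correlation). LOC_Os04g35160 in that list, called present on 2 of the 3 arrays before Al, rose by 1.88 ± 0.13, and the zinc transporter LOC_Os05g10940 by 0.87 ± 0.11.

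Over all genes, 7639 of 25283 tested probe sets differed (limma, adjusted p under 0.05), 3626 higher and 4013 lower after Al. Changes of at least 2-fold were found for 1151 probe sets higher and 637 lower, so 64.4% of these large changes were rises. At least 8-fold changes numbered 168 higher and 17 lower. Counted by gene, 3011 genes were higher and 3324 lower, with 958 and 499 at least 2-fold. The 2-fold higher count fell to 746 where presence on all 6 arrays was required, which leaves out genes absent before Al. The median log2 change of all tested probe sets was -0.04. In the authors' deposited table, 1455 probe sets had a p-value under 0.05 and a fold of 2 or more, and 1241 a fold of 0.5 or less, over all 57258. Among probe sets present on at least 3 arrays, those counts of the authors' deposited table were 1049 and 569. They rest on an unadjusted test with unequal variances and on mean linear signals, unlike the limma counts. With Benjamini-Hochberg adjustment over all probe sets, 1254 of the deposited p-values were under 0.05, whatever the fold.

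The largest rises included genes that were not called present before Al. OsWRKY22 (LOC_Os01g60490, chromosome 1, 35308316 to 35312296) was not called present on the 3 arrays before Al and was at 8.44 ± 0.35 (log2, SD, n = 3) after it, at least 53.1-fold higher. An ornithine decarboxylase (LOC_Os09g37120, chromosome 9, 21408789 to 21410016), an enzyme of polyamine synthesis, rose at least 73.4-fold (95% interval of the log2 change 5.82 to 6.58). An anthranilate N-benzoyltransferase (LOC_Os04g56900) rose at least 35.0-fold, a protein phosphatase 2C (LOC_Os06g48300) at least 36.7-fold and an F-box protein (LOC_Os03g43770) at least 19.1-fold.

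Among genes present before Al, the CYP72A1-like cytochrome P450 LOC_Os01g43750 (chromosome 1, 25393100 to 25395129) went from 7.51 ± 0.07 to 14.17 ± 0.10 (log2, SD, n = 3), a fold of 101.3. The ABA-responsive protein LOC_Os12g29400 rose by 6.60 ± 0.13 on the log2 scale. The adjacent abscisic stress ripening genes LOC_Os01g72900 and LOC_Os01g72910, called present on 2 of the 3 arrays before Al, rose by 6.68 ± 0.19 and 6.17 ± 0.17. The glucosyltransferase LOC_Os01g41430 rose by 5.81 ± 0.21 and the blue copper protein LOC_Os08g37660 by 5.59 ± 0.14. The probe sets of LOC_Os01g43750, LOC_Os12g29400 and the ornithine decarboxylase LOC_Os09g37120 are marked as shared, so similar genes may add to their signals.

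The largest falls included 2 HKT cation transporters, a family that carries sodium and potassium. LOC_Os06g48810 (HKT1, chromosome 6, 29538099 to 29558868) dropped from 13.09 ± 0.04 to 9.48 ± 0.19 (log2, SD, n = 3). LOC_Os04g51820 (HKT4) was present on 3 arrays before Al and 0 after it, at least 20.5-fold lower (95% interval of the log2 change -5.00 to -3.71). The aquaporin PIP2.3 gene LOC_Os04g44060 fell by 3.36 ± 0.10 on the log2 scale, a heat shock protein binding protein (LOC_Os07g49000) fell by 3.50 ± 0.15 and a metal ion binding protein (LOC_Os05g45820) fell by 3.17 ± 0.14. The lipid phosphate phosphatase LOC_Os01g47580 fell by 2.88 ± 0.11, and the alpha-amylase LOC_Os08g36910, called present on 1 of the 3 arrays after Al, fell by 3.56 ± 0.67. LOC_Os08g36910 fell by 2.93 without the first array before Al and fell by 4.49 without the second. The DNA binding protein LOC_Os11g39000 was at least 24.6-fold lower, the TIGR01568 family protein LOC_Os02g45620 at least 12.7-fold and the kinase LOC_Os04g34330 at least 6.44-fold, none of them called present after Al. A second DNA binding protein (LOC_Os01g34060), at 5.98 ± 0.56 (log2, SD, n = 3) before Al, was likewise not called present after it. Among these falls, the probe sets of LOC_Os06g48810, LOC_Os04g44060, LOC_Os08g36910 and LOC_Os01g34060 are marked as shared, so similar genes may add to their signals.

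Several families of transcription factors had more risers than fallers. Of 59 measured WRKY genes, 26 rose and 3 fell (27 and 7 adjusted over the list alone), and 20 rose at least 2-fold. OsWRKY77 (LOC_Os01g40260) rose at least 26.7-fold, OsWRKY53 (LOC_Os05g27730) by 1.17 ± 0.07 on the log2 scale and OsWRKY74 (LOC_Os09g16510) by 1.07 ± 0.06. The WRKY list passed camera (adjusted p = 6.96e-06, but adjusted p = 0.181 with an estimated correlation). Of 31 AP2/ERF factors, many of them ethylene-responsive, 17 rose and 4 fell (18 and 4 adjusted over the list alone), with LOC_Os05g29810 higher by 2.41 ± 0.13 and LOC_Os01g54890 by 2.20 ± 0.19. That list passed at adjusted p = 0.000326, but had adjusted p = 0.153 with an estimated correlation. Of 42 NAC factors, 20 rose and 6 fell (21 and 7 adjusted over the list alone), with LOC_Os07g12340 higher by 2.86 ± 0.16 and LOC_Os12g03050 by 1.98 ± 0.14 (camera adjusted p = 0.0101, but adjusted p = 0.181 with an estimated correlation). The 88 measured MYB genes went both ways, with 16 higher and 19 lower (17 and 19 adjusted over the list alone), and did not pass (camera adjusted p = 0.643). LOC_Os01g09280 in that family rose by 1.55 ± 0.09 and LOC_Os07g44090 fell by 1.47 ± 0.09.

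Genes of the jasmonate pathway were mostly higher after Al. Of 32 measured, 18 rose and 6 fell (21 and 6 adjusted over the list alone), with a median log2 change of 0.57. The ZIM motif genes LOC_Os03g08310, LOC_Os03g08330 and LOC_Os09g23660, of the family of jasmonate repressors, rose by 2.97 ± 0.14, 2.58 ± 0.11 and 1.55 ± 0.07, and the lipoxygenase LOC_Os03g49380 by 0.82 ± 0.05. The list passed camera (adjusted p = 6.96e-06, but adjusted p = 0.153 with an estimated correlation). Ethylene synthesis genes did not pass as a list, with 5 higher and 3 lower of 16 (7 and 5 adjusted over the list alone; camera adjusted p = 0.546). Auxin genes did not pass either, with 20 higher and 24 lower of 108 (22 and 28 adjusted over the list alone; camera adjusted p = 0.804). Their median was slightly below 0 while their mean and test lay above it. The auxin efflux carrier family gene LOC_Os09g38130 fell by 1.72 ± 0.07, and the auxin-inducible gene LOC_Os01g66530 was at least 14.9-fold higher.

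The lists of cytochrome P450 genes, glutathione S-transferases and ABC transporters had more risers than fallers. Of 91 cytochrome P450 genes, 32 rose and 13 fell (34 and 15 adjusted over the list alone), and 21 rose at least 2-fold. LOC_Os01g43720, of the same CYP72A1 type as the P450 gene named above, rose by 5.35 ± 0.08, and LOC_Os03g55240 by 3.09 ± 0.10. The P450 list passed camera (adjusted p = 0.00100, but adjusted p = 0.0714 with an estimated correlation). Of 52 glutathione S-transferases, which conjugate glutathione to toxic compounds, 20 rose and 3 fell (20 and 3 adjusted over the list alone). LOC_Os10g38501 rose by 2.58 ± 0.11 and LOC_Os10g38360 by 2.33 ± 0.08 (list camera adjusted p = 0.000326, but adjusted p = 0.181 with an estimated correlation). Of 37 ABC transporters, 14 rose and 5 fell (16 and 5 adjusted over the list alone). The PDR5-like transporter LOC_Os01g42380, called present on 1 of the 3 arrays before Al, rose by 5.08 ± 0.13 and LOC_Os01g07870 by 2.15 ± 0.11 (list camera adjusted p = 0.00345, but adjusted p = 0.153 with an estimated correlation).

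In the phenylpropanoid and lignin list, 6 of 24 rose and 4 fell (7 and 4 adjusted over the list alone). The phenylalanine ammonia-lyases LOC_Os02g41670 and LOC_Os04g43800, which catalyse the first step of the pathway, rose by 3.63 ± 0.15 and 2.33 ± 0.12, and the 4-coumarate CoA ligase LOC_Os08g34790 by 2.18 ± 0.09. That list passed narrowly (camera adjusted p = 0.0407, but adjusted p = 0.181 with an estimated correlation). Its call was also lost without the second array after Al (0.0699), without the first array before it (0.0683), without the intensity trend (0.0845) and with the probe set of smallest p for each gene (0.0529). Without the filter on dim probe sets its adjusted p was 0.0851 and its median log2 change went from 0.11 to -0.01. Fermentation genes had 3 higher and 1 lower of 7 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0276, but adjusted p = 0.289 with an estimated correlation). Their call was lost without the second array after Al (0.0621). The pyruvate decarboxylase LOC_Os01g06660 rose by 2.07 ± 0.14.

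**Figure D2:**
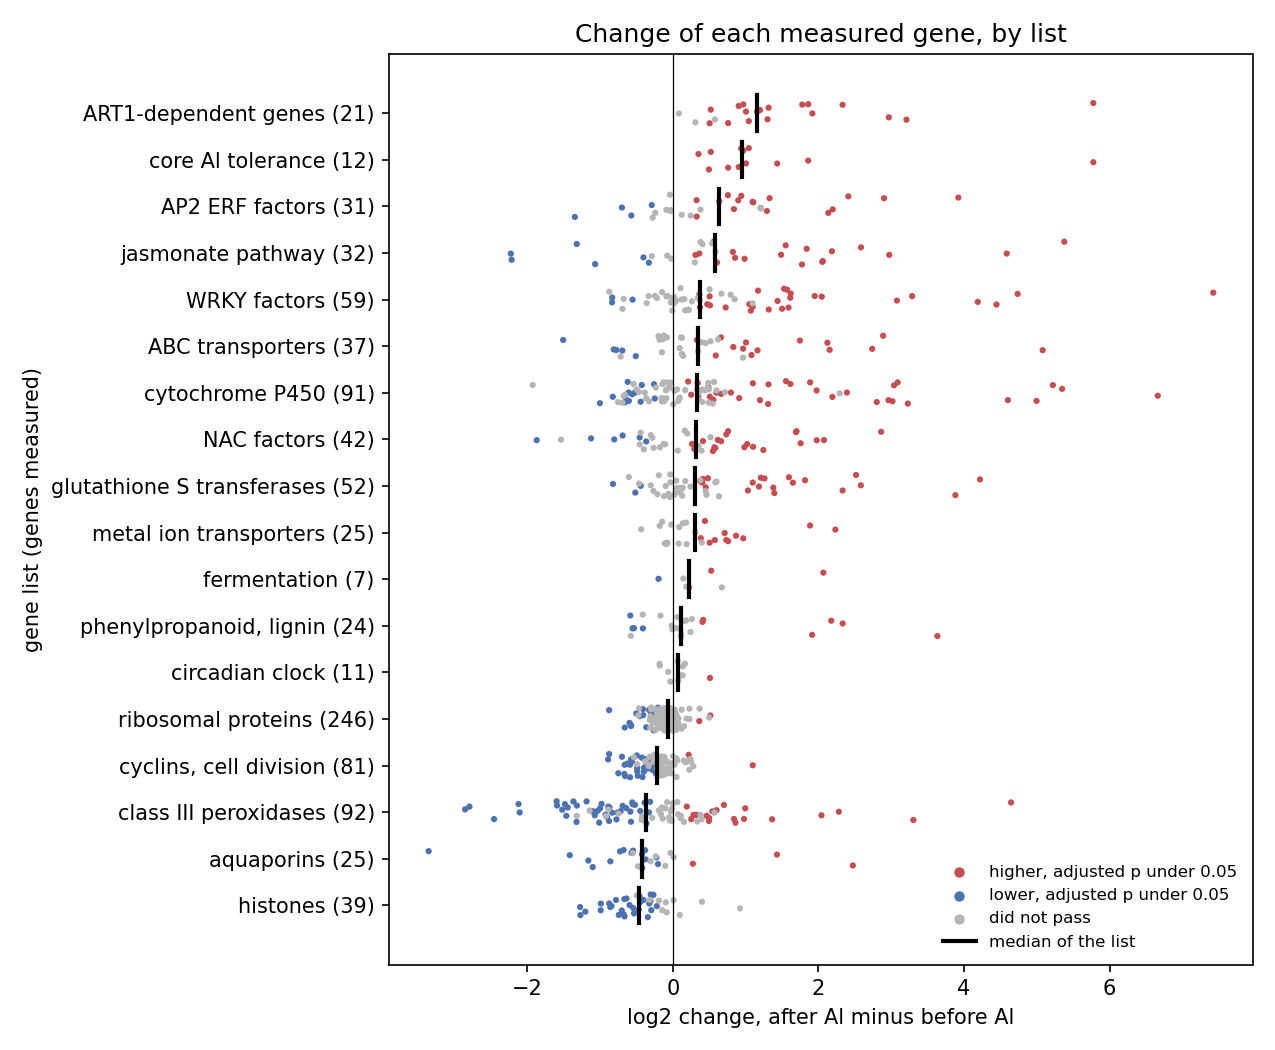
Log2 change after Al minus before Al (horizontal axis) of each measured gene in the 17 gene lists that passed camera at the preset correlation and in the clock list (vertical axis, with the number of genes measured). Each point is 1 gene, red if higher, blue if lower and grey if it did not pass limma, and black bars are list medians, from -0.47 for the histones to 1.16 for the ART1-dependent genes.

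Histone genes were lower after Al. Of 39 measured, 0 rose and 29 fell (0 and 30 adjusted over the list alone), with a median log2 change of -0.47. The histone H3 gene LOC_Os11g05730 fell by 1.27 ± 0.06, and the H4 genes LOC_Os05g38740 and LOC_Os09g26340 fell by 1.20 ± 0.06 and 0.64 ± 0.05. The list passed camera (adjusted p = 2.22e-09, but adjusted p = 0.0714 with an estimated correlation). Of 81 cyclin and cell division genes, 2 rose and 30 fell (3 and 32 adjusted over the list alone), among them the cyclin delta-2 genes LOC_Os09g29100 and LOC_Os03g42070, which fell by 0.67 ± 0.06 and 0.70 ± 0.09. That list passed at adjusted p = 0.000385, but had adjusted p = 0.160 with an estimated correlation. Its word search also took in kinesin light chain genes, subunits of a microtubule motor, such as LOC_Os02g47880, which fell by 0.88 ± 0.06.

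Other markers of root tissue were measured beside the division genes. OsPIN2, an auxin carrier of the epidermis, fell by 0.35 ± 0.08, and the ground tissue factor OsSCR1 fell by 0.93 ± 0.20. Lsi1, a silicon channel of mature root, had a log2 change of -0.31 ± 0.10 and missed the threshold (limma, adjusted p = 0.0509), although it passed in some of the alternatives. The quiescent centre gene QHB (0.21 ± 0.17) and OsSHR1 (-0.08 ± 0.10) did not pass, and the list of 5 did not pass camera (adjusted p = 0.268), with 0 higher and 2 lower (0 and 3 adjusted over the list alone). Of 17 photosynthesis genes, markers of green tissue, 1 was higher and 4 were lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.525). The Rubisco small subunit gene LOC_Os02g05830 was present on 3 arrays before Al and 0 after it, at least 8.83-fold lower.

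The aquaporin and class III peroxidase lists had more fallers than risers. Of 25 aquaporins, 3 rose and 15 fell (3 and 17 adjusted over the list alone), with a median log2 change of -0.42. Against the PIP2.3 gene and the NIP gene LOC_Os06g12310, which fell by 1.42 ± 0.06, the TIP4.1 gene LOC_Os05g14240 rose by 2.47 ± 0.07 and the NIP gene LOC_Os05g11560 by 1.43 ± 0.09. The aquaporin list passed camera (adjusted p = 0.000924, but adjusted p = 0.181 with an estimated correlation). Of 92 class III peroxidases, secreted enzymes that act on the cell wall, 20 rose and 42 fell (21 and 45 adjusted over the list alone). LOC_Os10g02040 fell by 2.46 ± 0.08 and LOC_Os06g35520 fell by 2.12 ± 0.08, while LOC_Os12g02080 rose by 3.30 ± 0.13 and LOC_Os01g73200 at least 25.0-fold. The peroxidase list passed at adjusted p = 0.00187, but had adjusted p = 0.181 with an estimated correlation. Of 246 ribosomal protein genes, 2 rose and 32 fell (1 and 9 adjusted over the list alone), with a median of only -0.07. The ribosomal list passed camera (adjusted p = 0.00312, but adjusted p = 0.508 with an estimated correlation), and a split of the arrays across the groups gave it a smaller adjusted p (2.38e-11).

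Cell wall lists did not pass as a whole but held large single changes. Of 43 pectin-modifying genes, 8 rose and 14 fell (8 and 17 adjusted over the list alone; camera adjusted p = 0.0897). The pectinesterase LOC_Os10g10620 fell by 2.71 ± 0.11 and the polygalacturonase LOC_Os01g44970 fell by 1.68 ± 0.12. Of 53 expansin and xyloglucan endotransglucosylase genes, 10 rose and 18 fell (12 and 21 adjusted over the list alone; camera adjusted p = 0.238), with LOC_Os04g51460 at least 15.1-fold higher. Of 30 cellulose synthase and related genes, 4 rose and 10 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.165). CSLF8 (LOC_Os07g36630) fell by 2.83 ± 0.13 and CSLF3 (LOC_Os07g36750) rose by 1.03 ± 0.06.

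Organic acid enzymes and several signalling families did not pass as lists. Of 38 measured, 3 rose and 5 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.918), and their median and test lay below 0 while their mean lay above it. Of the organic acid enzymes, the NADP-dependent malic enzyme LOC_Os05g09440 rose by 4.43 ± 0.11. Of 147 calcium signalling genes, 44 rose and 35 fell (47 and 41 adjusted over the list alone; camera adjusted p = 0.268), with the calmodulin-like gene LOC_Os01g72530 higher by 3.51 ± 0.11. Of 136 receptor-like kinases, 34 rose and 23 fell (35 and 28 adjusted over the list alone; camera adjusted p = 0.268), with LOC_Os11g10290 higher by 3.20 ± 0.09. Of 80 pathogenesis-related genes, 24 rose and 22 fell (25 and 27 adjusted over the list alone; camera adjusted p = 0.639). LOC_Os03g18850 in that list rose by 2.00 ± 0.08 and LOC_Os02g54540 fell by 2.06 ± 0.07.

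Antioxidant, heat shock and proteasome genes did not pass as lists either. Of 94 redox and antioxidant genes, 14 rose and 13 fell (14 and 13 adjusted over the list alone; camera adjusted p = 0.360), with the monodehydroascorbate reductase LOC_Os08g44340 higher by 0.90 ± 0.06. Of 134 heat shock genes, 23 rose and 21 fell (23 and 21 adjusted over the list alone; camera adjusted p = 0.639), and their median and mean lay just below 0 while the test pointed up. Of 45 proteasome genes, 2 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.145).

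Metallothionein and metal chelation genes had 8 higher and 3 lower of 17 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0897), a list that passed without the filter on dim probe sets (0.0475), without the first array after Al (0.0412) and without the second before it (0.0243). At an estimated correlation that list had adjusted p = 0.508 with all arrays. Sulfate transport and glutathione synthesis genes had 7 higher and 4 lower of 22 (7 and 4 adjusted over the list alone; camera adjusted p = 0.217). Phosphate starvation genes had 7 higher and 6 lower of 28 (8 and 7 adjusted over the list alone; camera adjusted p = 0.757), with a median below 0 and a mean and test above it. Sucrose and starch genes had 5 higher and 11 lower of 43 (5 and 11 adjusted over the list alone; camera adjusted p = 0.525). LEA and dehydrin genes had 1 higher and 1 lower of 6 (1 and 1 adjusted over the list alone; camera adjusted p = 0.795). UDP-glycosyltransferases had 0 higher and 2 lower of 5 (0 and 2 adjusted over the list alone; camera adjusted p = 0.504). That word search left out other glucosyltransferases, such as LOC_Os01g41430 named above, which rose by 5.81 ± 0.21. Those 5 genes thus do not stand for all such enzymes.

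Clock genes were measured because time of day can differ between harvests. Of 11, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.449). OsLUX rose by 0.51 ± 0.10, and the other log2 changes ran from -0.18 ± 0.07 for OsPRR37 to 0.17 ± 0.06 for OsLHY, with 1 probe set per gene. Second probe sets of OsPRR37 and OsELF3-1 gave larger log2 changes, of -0.88 ± 0.33 for OsPRR37 (limma, adjusted p = 0.0755) and -0.38 ± 0.17 for OsELF3-1 (limma, adjusted p = 0.136), which did not pass. OsLHY passed without the first array before Al (limma, adjusted p = 0.0388) and OsGI (0.14 ± 0.07) without the third after Al (0.0468).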

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

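The 15 alternatives were chosen before the data were examined. The 13 that refit the probe sets kept the count of calls within 1.5 times its value of 7639, from 6206 with an array left out to 7844 with the repeat number as a block, and no call changed sign. Of the 7639 calls, between 6014 and 7622 kept their call and direction in the fits on the same probe sets. Leaving out each array in turn gave 1714 to 1838 calls of at least 2-fold and 15 to 18 lists. Lists passing fell from 17 to 2 with an estimated correlation between genes, a setting that also tests on only 4 residual degrees of freedom. The count of probe sets at least 2-fold higher fell from 1151 to 746 when presence on all 6 arrays was required, a filter that leaves out genes absent before Al. Of the lists that passed, the phenylpropanoid and lignin list had its median turn from 0.11 to -0.01 without the filter on dim probe sets, where it lost its call, and some lists that did not pass had medians near 0 that changed sign. No scaling moved the median change of all probe sets by more than 0.1 on the log2 scale. Of the named genes, 5 lost their call in some setting and 3 gained one. The equal repeat numbers of the sample titles were checked as pairs, and the deviations of same-numbered arrays correlated at 0.0696, 0.00114 and 0.0865. The treated arrays carry numbers higher by 1 in the value columns. By those, array 2 before Al correlated with the first after it at 0.0212, and array 3 with the second at 0.00695. Arrays with different title numbers correlated at -0.0920 to 0.0212. The numbers alone thus do not establish pairs, and a weak pairing by title number is not excluded. With the repeat number as a block, 7844 probe sets passed, 1827 of them at least 2-fold, and 18 lists, among them the metallothionein and metal chelation list (adjusted p = 0.0268, but adjusted p = 0.508 with an estimated correlation and no block). Lsi1 passed with it too (adjusted p = 0.00355). By the titles, repeats 1 and 3, but not repeat 2, matched their own number best. Dim probe sets limit the lower end. The 27428 probe sets present on no array had medians of 2.82 and 2.73 on the first 2 arrays after Al and of 3.04 to 3.10 on the other 4.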

Other observations

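The scan of gene families, the counts of calls over splits and the clock, ART1, time in solution and tissue tests were chosen only after their results had been seen. A scan of 259 families of at least 8 genes that share a product description, chosen after the data were seen, found 19 that passed camera at the preset correlation and 0 with an estimated one (limma). With 4 residual degrees of freedom and 259 families, a pass at the estimated setting was hard to reach, so the 0 decides little. The histone family, with 0 higher and 27 lower of 34, had adjusted p = 5.26e-08 at the preset correlation and 0.6275 with an estimated one. Of 11 VQ motif genes, whose proteins bind WRKY factors, 8 rose and 0 fell (adjusted p = 0.000610, but adjusted p = 0.704 with an estimated correlation). LOC_Os03g20330, present on 1 of the 3 arrays before Al, rose by 3.93 ± 0.24 and LOC_Os06g45570 by 2.45 ± 0.23. Of 8 xylanase inhibitor genes, 4 rose and 0 fell (adjusted p = 0.0429, but adjusted p = 0.704 with an estimated correlation), with LOC_Os11g47600, not called present before Al, at least 26.5-fold higher (16.6-fold without the second array before Al).

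Some families had more fallers than risers. Of 13 glycine-rich cell wall structural protein genes, all on chromosome 10, 0 rose and 9 fell (adjusted p = 0.00456, but adjusted p = 0.704 with an estimated correlation), and LOC_Os10g31670 fell by 1.65 ± 0.24. Shared probes were not tested on this family. Of 8 beta-galactosidase genes, 0 rose and 7 fell (adjusted p = 0.00498, but adjusted p = 0.678 with an estimated correlation), and LOC_Os03g15020 fell by 1.32 ± 0.07 and LOC_Os06g37560 fell by 1.23 ± 0.06. Of 21 receptor protein kinases of the CRINKLY4, CLAVATA1, TMK1 and PERK1 types, 2 rose and 12 fell (adjusted p = 0.00581, but adjusted p = 0.678 with an estimated correlation). The CRINKLY4-type gene LOC_Os01g70410 fell by 1.47 ± 0.07. Of 8 lectin-like receptor kinases, in contrast, 4 rose and 0 fell (adjusted p = 0.0461, but adjusted p = 0.704 with an estimated correlation).

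The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 7639 calls and 1788 of at least 2-fold, and 1 split, the real one, reached each count. The highest of the other splits was 0 for both (limma; 285 to 948 probe sets at an unadjusted p under 0.05, against 10038). For lists passing camera at the preset correlation, 2 of the 10 splits reached the real count of 17, since the split that put array 1 before Al with arrays 2 and 3 after Al also gave 17. The other splits hold 2 arrays of one group and 1 of the other on each side, so part of the difference between the groups remains in them. That difference also widens the spread within each side, which lowers the calls of single probe sets. Their 0 calls are thus not a measure of what chance alone would give. Of the 17 lists, 15 had their smallest adjusted p in the real split, and the ribosomal and fermentation lists did not. Most of the 17 also passed in some of the 9 other splits, the ART1-dependent list in 9, the histones in 8, the core list in 6, and the aquaporin, WRKY and metal ion transporter lists in 5 each, so a pass at the preset correlation alone does not set the real split apart. The ART1-dependent list reached 0.000244 and the core list 0.00162 in another split, against 4.4e-14 and 2.16e-09.

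The rise of the core Al tolerance genes was weighed against a clock shift and the time in solution. The median size of change of the 11 clock genes was 0.13 on the log2 scale, against a median rise of 0.95 in the core genes. It lay at percentile 20.5 of 10000 random lists matched on brightness (14.8 with all 14 tested clock probe sets, added after the first was seen). That is inside their central 95%, from 0.08 to 0.43. The random lists carry the same difference between the groups, and whether the clock genes cycle in these tips was not tested. The test therefore cannot decide on a shift of the clock. Exposure to Al predicts a rise of ART1-dependent genes, and the 13 of them outside the core list, taken after the rise of the whole list was seen, had a median of 1.30, above the central 95% of matched lists (upper bound 0.22), which does not separate Al from time or pH. The 6 h in solution and its pH cannot be told apart from Al, because 0 arrays were kept as long without Al. Al exposure thus stays a candidate explanation beside these and a shift of the clock.

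The fall of histone and cell division genes was weighed against the array's scale and the tissue sampled. The histone median of -0.47 lay at percentile 0 of 10000 lists matched on brightness, whose central 95% ran from -0.10 to 0.05. A shift shared by genes of like brightness thus does not account for the fall. Compression of bright signals would shrink a fall rather than make one, so these lists do not test it as a cause. A larger share of mature tissue in the tips could lower division genes and would raise genes abundant outside the meristem. The class III peroxidases had a median of -0.376 and the aquaporins one of -0.42, which goes against it, but these lists lost their calls with an estimated correlation and may respond to the treatment themselves. A smaller share of dividing cells and lower transcript levels within them cannot be told apart here, and an effect of Al on division stays an untested hypothesis.

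Genes at least 2-fold higher were neighbours more often than in shuffled gene orders. Neighbours were measured genes that follow each other in locus number, at most 100 apart, so unmeasured genes can lie between them. Among 18131 genes with a locus number, 104 neighbouring pairs were both at least 2-fold higher, against a mean of 45.1 in 10000 shuffles (p = 1e-04, one-sided, permutation test, the smallest they can give). With pairs of the same product name and probe sets marked as shared left out, 52 pairs remained against a 95th percentile of 45, which argues against shared probes as the whole source. The margin shrank to 43 against 42 without pairs of 2 unnamed proteins, a limit added after the 52 was seen, and related neighbours under different names stayed in, so a part from duplicated genes may remain. Runs chosen after their values were seen include 3 CYP72A1 genes from LOC_Os01g43720 to LOC_Os01g43750, higher by 5.00 to 6.66, which share a product name and so were left out of the count of 52, and OsFRDL4 with its neighbours up to the sucrose-phosphate synthase LOC_Os01g69030.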
